A study of Ovis aries with 24 samples.

How the data were processed

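Total RNA from the ductus arteriosus and the ascending aorta of sheep was labelled with Cy3 and hybridised to single-colour Agilent arrays, 1 sample per array, per the labels. Groups were taken from the labels: 2 vessels at 3 stages, with 4 arrays in each of 6 groups. The labels give 97 and 136 days of gestation for the preterm and near-term fetuses, while the sample titles give 100 and 140, and 12 hours for the newborns. The labels speak of 4 animals per group and do not say that the ductus and aorta with the same number came from 1 animal.

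The values are spot intensity on a linear scale, the processed signal after background subtraction and spatial detrending by Agilent Feature Extraction 9.5.3.1 (protocol GE1-v5_95_Feb07, array design 019921), per the file headers. No further normalisation is recorded in the sources used here. Each array had 15744 spots, 15208 of them non-control spots for 15008 probes. The 75th percentile of the processed signal ran from 322.1 to 1143, the median from 58.5 to 298.9, and saturated spots numbered 0 or 1 per array. The number of arrays limits the precision. Among 276 pairs of arrays 0 held identical values, and correlations across probes were 0.866 to 0.985 within groups and 0.823 to 0.981 between groups.

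Control spots and spots marked as non-uniform or as population outliers (2 to 124 per array) were left out, the log2 processed signal was set relative to the 75th percentile of its array, and spots of 1 probe were averaged. A probe was tested if well above background on at least 4 of the 24 arrays, which left 13997. Where a probe was well above background on 0 arrays of a group, the fold is given as "at least", from the mean of the brighter group against the mean, over the arrays of the dim group, of the higher of the lowest signal among probes well above background and the probe's own signal. Such a fold allows for the floor of the arrays under the main processing only. It leaves out sampling error, is not a lower confidence limit and can exceed the fold under an alternative. The symbol of a probe came from the array's own names and from RefSeq names of the assembly ARS-UI_Ramb_v3.0, of which no coordinates are used. Of 563 probes with a RefSeq accession 544 matched that table, and 1465 probes received 1 of 828 symbols: 518 by RefSeq accession, 104 by gene ID, 454 by a gene name equal to a reference symbol, 37 by a synonym, 57 with the array's name kept, and 210 and 85 by a table made by hand from the array's gene names and GenBank descriptions. The other 13543 probes carry an accession only and are unnamed here. The table made by hand was written from the array's annotation after the comparisons were fixed and before any of them was computed. A gene with several probes is represented by the probe with the highest mean log2 signal.

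All 24 arrays entered 1 limma fit of 6 group means (limma 3.58.1, R 4.3.3, lmFit and eBayes, two-sided), from which 9 comparisons were taken: ductus minus aorta at each stage, the change between successive stages in each vessel, and the 2 differences of these changes between the vessels. Adjusted p-values are Benjamini-Hochberg within a comparison, with calls at 0.05, and errors given after ± are standard errors of the fit unless marked SD. The comparisons, tests, filters, gene lists and the rule for named genes were fixed before the data were examined. Of 34 gene lists 22 had at least 5 measured members and were tested with limma's camera over 785 named genes at a preset correlation of 0.01, adjusted over the lists within a comparison. In all, 24 list tests passed, 0 of them with an estimated correlation and 14 of them also with fry, which called 17 in all and tests whether the genes of a list move one way and does not set them against other genes. The lists described in each comparison were chosen after the list results were seen. A count adjusted over the list alone is given where it differs from the count over all probes.

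The named genes were the 8 largest rises and 8 largest falls among called genes whose 4 and 4 arrays did not overlap (5 and 5 for the aorta between stages and for the differences between the vessels, without the overlap condition for the latter), the 2 to 4 members with the smallest p of each described list, and a fixed panel of genes of the ductus. Not every gene that this rule names is reported here. The script was tested on simulated data: of changes of 1 and 2 on the log2 scale it recovered 35% and 66% for the newborn ductus against aorta, 33% and 71% for the aorta between preterm and near term, and 12% and 51% for the difference between the vessels at birth. False calls were 3 of 104 and 3 of 107 in the first 2 of these, and 0 probes were called where nothing was changed. The simulated noise was independent for each probe and array. Variation shared by many probes, which these arrays hold, was not simulated, so these rates do not cover it.

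Alternatives were normexp background correction (offset 50), quantile normalisation, median centring, no filter or a filter on all 24 arrays, marked spots kept, replicate blocks, fits of only the groups compared, trend and robust settings, array weights, 1 probe per named gene, and each array left out in turn. Added after the data were seen were the spike-in detection limit and the percent of spots above background as covariates, a fit of only the arrays with a limit under 1.5, and array weights with missing values filled. The setting of 1 probe per named gene gave counts only, and a gene removed by the filter on all 24 arrays was not tested there. For a gene, "each alternative" therefore means each one in which it was tested. Figures were drawn with matplotlib 3.10.9, and tables prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.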

Results

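RNA was measured in the ductus arteriosus, the fetal vessel that carries blood from the pulmonary artery to the aorta and closes after birth, and in a piece of ascending aorta from sheep at 3 stages. The stages were preterm fetuses of 97 days of gestation, near-term fetuses of 136 days and newborn lambs of 12 hours. Each of the 6 groups held 4 arrays from 4 animals, so that n = 4 per group applies to every value given here unless arrays are said to be left out. Each of the 24 single-colour Agilent arrays carried 15208 non-control spots for 15008 probes, of which 13997 were tested and 1465 could be given a gene symbol. The named genes tested numbered 785, and their number and that of the arrays limit what could be seen.

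The share of spots well above background ran from 66.2% on near-term ductus replicate 4 to 94.4% on near-term ductus replicate 3. The first principal component held 65.3% of the variance and parted the arrays by the detection limit of the spike-in controls: 12 arrays with a limit above 1.5 scored 22.8 to 153.9, and 12 with a limit under 1.5 scored −111.8 to −3.3. Arrays above 1.5 numbered 3 in preterm aorta, 3 in near-term aorta, 2 in newborn aorta, 2 in preterm ductus, 2 in near-term ductus and 0 in newborn ductus. The second component set the 8 newborn arrays (lowest score 28.3) apart from the fetal arrays (highest 16.2). The 8 arrays of each stage shared 1 slide, and all ductus arrays lay in column 1 and all aorta arrays in column 2 of their slide, so that stage and slide, and vessel and column, cannot be told apart. For the genes named here, 1 of the 4 arrays stood apart by Dixon's test in 20 of 303 groups, against 15.2 by chance. Dim genes depended on the background correction, and with normexp the fold moved by over 1.5 times for 50 of 119 calls of named genes.

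**Figure D1:**
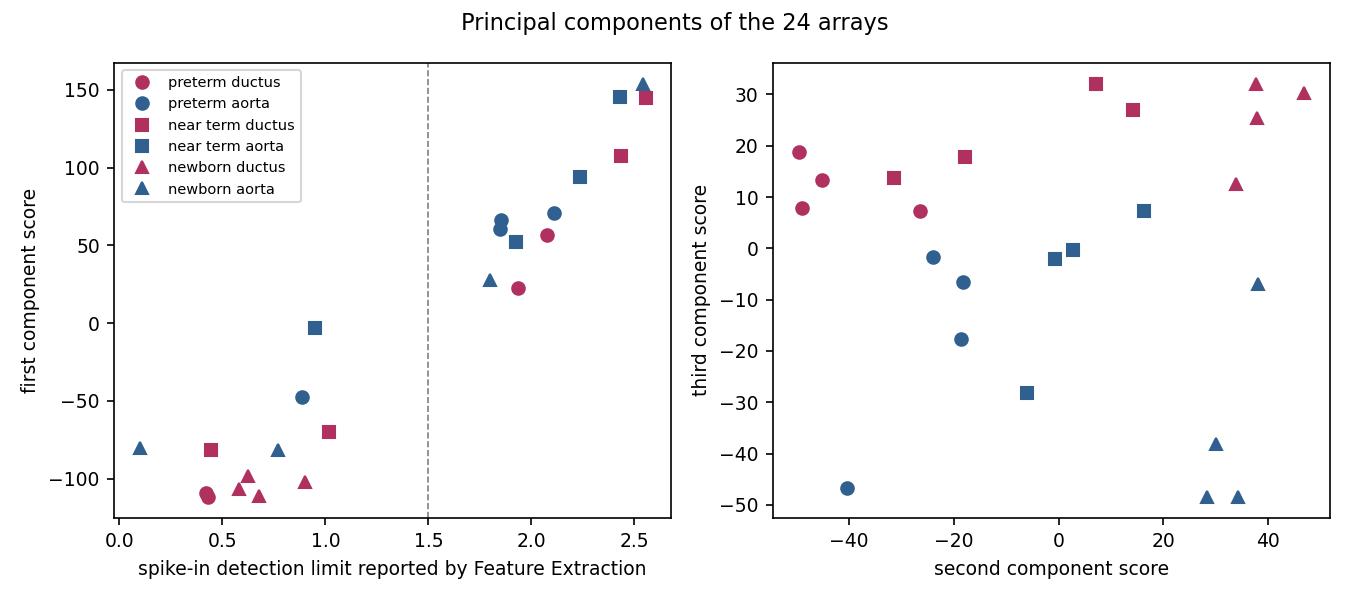
Principal component scores of the 24 arrays, with colour for the vessel and symbol for the stage; the left panel plots the score on the first component against the spike-in detection limit reported by Feature Extraction (dashed line at 1.5), the right panel the third against the second component, all in arbitrary units. Arrays with a limit above 1.5 score 22.8 or more on the first component, and the newborn arrays score 28.3 or more on the second.

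**Figure D2:**
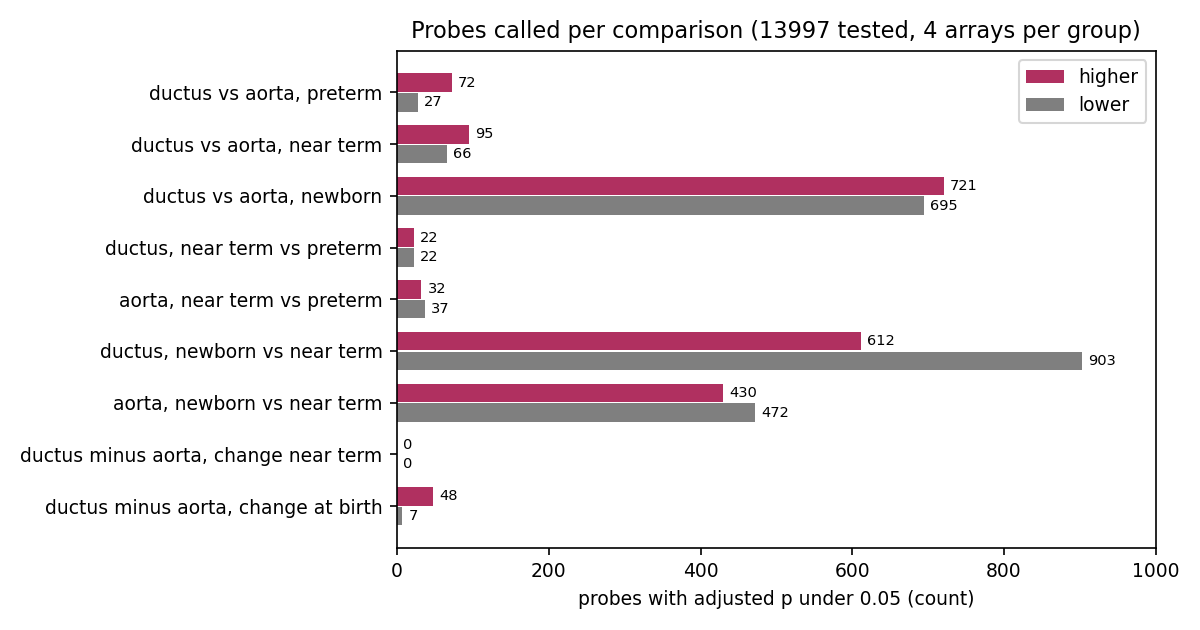
Number of probes (x axis, count from 0) with an adjusted p under 0.05 in each of the 9 comparisons, with higher and lower calls as separate bars. The newborn ductus against the newborn aorta had 721 higher and 695 lower, and the ductus after birth against near term had 612 higher and 903 lower.

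In preterm fetuses the ductus was set against the aorta to find transcripts that already separated the vessels at this stage. IL1A, which encodes the inflammatory cytokine interleukin 1 alpha, was 16.9-fold higher in the ductus (log2 difference 4.08 ± 0.73 SE, adjusted p = 0.00713). It was well above background on 3 of the 4 aorta arrays. EDN1, which encodes the vasoconstrictor peptide endothelin 1, was 3.94-fold higher, at a normalised log2 signal of −1.54 ± 0.31 (SD, n = 4) in the ductus and −3.52 ± 0.28 in the aorta (adjusted p = 0.00456). ALDH1A1, an enzyme of retinoic acid synthesis, was 2.19-fold higher (1.13 ± 0.26, adjusted p = 0.049). INHBA, a subunit of activin, was 2.17-fold higher (1.12 ± 0.20, adjusted p = 0.00882). The receptors TLR4, which binds bacterial lipopolysaccharide, and NPY1R, which binds neuropeptide Y, were each 2.74-fold lower in the ductus (adjusted p = 0.00976 and 0.049). The homeobox gene HOXA7 was 2.4-fold lower (0.0333) and the amino acid transaminase gene BCAT1 2.34-fold lower (0.0468).

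For these 8 genes all 4 arrays of one vessel lay beyond all 4 of the other. Among 13997 probes, 99 passed in limma, 72 higher and 27 lower, and 8 of the 785 named genes did. Of 6 measured patterning genes of the neural crest and outflow vessels, 0 passed over all probes (1 with median centring or quantile normalisation) and 3 were higher when adjusted over the list alone. TFAP2A, a neural crest transcription factor, was at least 1.67-fold higher (adjusted p = 0.203), HOXA4 differed by 0.92 ± 0.28 (0.174) and SNAI2 by 0.51 ± 0.20 (0.343). The list as a whole lay above other genes in camera (adjusted p = 0.00522, and adjusted p = 0.446 with an estimated correlation). Glycolytic enzymes also lay above other genes (adjusted p = 0.0326, and adjusted p = 0.446 with an estimated correlation), although 0 of 6 passed singly or over the list alone. LDHA differed by 0.79 ± 0.28 (adjusted p = 0.296) and GAPDH by 0.38 ± 0.26 (0.565).

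Of 18 inflammatory genes IL1A was higher and TLR4 lower (1 higher and 2 lower when adjusted over the list alone). Of 11 vasoactive peptide and receptor genes EDN1 was higher and NPY1R lower, EDNRA differing by −1.21 ± 0.87 (adjusted p = 0.581). Of 9 genes of prostanoid synthesis, transport and reception 0 passed and 1 was higher over the list alone. PTGS2, the inducible cyclooxygenase, differed by 1.08 ± 0.30 (0.124) on its brighter probe and went the other way on its other probe. PTGS1, the constitutive cyclooxygenase, differed by 0.19 ± 0.20 (0.686), the prostaglandin E receptor PTGER4 by −0.65 ± 1.16 (0.81). The prostaglandin transporter SLCO2A1 differed by 0.07 ± 0.33 (0.94) and the endothelial nitric oxide synthase NOS3 by −0.49 ± 0.35 (0.573). The calls numbered 52, 53 and 57 without preterm aorta replicate 1, 2 or 3 and 58 and 64 without preterm ductus replicate 1 or 2, and the patterning and glycolysis calls ended under 3 of 16 and 9 of 17 alternatives (adjusted p up to 0.446), the latter also without preterm aorta replicate 1 (0.0611) or 2 (0.112) or preterm ductus replicate 2 (0.0685) or 3 (0.33). IL1A alone passed under each alternative and with each array left out, at 2.01 with normexp and 3.47 without preterm aorta replicate 1. Its 5.95 on the arrays with a limit under 1.5 set 2 ductus arrays against preterm aorta replicate 1 alone. That array stood apart for IL1A, at −7.21 against −4.99 to −4.58, so this fit adds little for the gene. EDN1 failed in this fit only. INHBA, NPY1R, TLR4, HOXA7, ALDH1A1 and BCAT1 failed under 4 to 7 of 14 or 15 alternatives. NPY1R, BCAT1 and ALDH1A1 failed with any array left out (up to 0.173), HOXA7 with 7 (up to 0.122) and TLR4 without preterm ductus replicate 1 (0.05).

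Near term, at 136 days, the same contrast again gave IL1A (12.9-fold, 3.69 ± 0.73, adjusted p = 0.0127), EDN1 (2.89-fold, 1.53 ± 0.34, 0.0262) and INHBA (1.98-fold, 0.99 ± 0.20, 0.0182) as higher in the ductus. IL1A was well above background on 2 of the 4 aorta arrays. PRLH, which encodes prolactin-releasing peptide, was 4.3-fold higher (2.11 ± 0.39, adjusted p = 0.00778). TNFRSF11B, which encodes osteoprotegerin, was 2.35-fold higher (adjusted p = 0.0191). The mast cell tryptase gene TPSB2 was 2.32-fold higher (0.0261). SNAI2, a transcription factor of the neural crest, was 2.14-fold higher (0.00773). The insulin-like growth factor binding protein gene IGFBP2 was 2.11-fold higher (0.0425). NPY1R was 3.86-fold lower (−1.95 ± 0.34, adjusted p = 0.005). AQP3, a water and glycerol channel, was 3.77-fold lower (−1.91 ± 0.44, 0.0343).

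For these 10 genes the arrays of the 2 vessels did not overlap. Calls numbered 161 probes, 95 higher and 66 lower, and 12 named genes. Of 6 patterning genes 1 passed, SNAI2, and 3 were higher over the list alone, HOXA5 differing by 1.11 ± 0.33 (adjusted p = 0.139) and HOXA4 by 0.86 ± 0.28 (0.22). As a list they lay above other genes in camera (adjusted p = 0.00113, and adjusted p = 0.47 with an estimated correlation). Of 21 genes of Notch, BMP and TGF-beta signalling only INHBA passed, BMP2 differing by 1.47 ± 0.48 (0.22) and BMP6 by 0.95 ± 0.32 (0.257). All 13 ribosomal protein genes lay below 0 (12 of 13 with quantile normalisation) while 0 passed. RPL32 differed by −0.45 ± 0.18 (0.429) and RPL13 by −0.41 ± 0.22 (0.766). This list lay below other genes in camera (adjusted p = 0.0368, and adjusted p = 0.76 with an estimated correlation).

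Of 11 vasoactive genes EDN1 was higher and NPY1R lower, and the angiotensin receptor AGTR1 differed by −0.62 ± 0.37 (adjusted p = 0.85). Of 9 prostanoid genes 0 passed and 2 were higher over the list alone, PTGS2 differing by 0.94 ± 0.30 (0.207) and PTGS1 by 0.62 ± 0.20 (0.237). NOS3 differed by 0.16 ± 0.35 (0.936). The calls numbered 105, 90 and 93 without near-term aorta replicate 1, 2 or 3 and 107, 70 and 94 without near-term ductus replicate 2, 3 or 4, the patterning and ribosomal calls ended under 3 of 16 and 7 of 17 alternatives (adjusted p up to 0.47 and 0.76), the latter also without near-term aorta replicate 1 (0.677) or near-term ductus replicate 1 (0.349) or 3 (0.527), and 2 of the 35 splits of these 8 arrays into 4 and 4, the real one included, called as many probes. None of the 10 genes kept its call throughout: normexp ended those of NPY1R (−0.83, adjusted p = 0.862), PRLH (0.90, 0.552), EDN1 (0.79, 0.433), SNAI2 (0.92, 0.102), INHBA, IGFBP2 and AQP3, a fit of only the groups compared ended all but IL1A (0.102 to 0.29), IL1A failed without near-term aorta replicate 1 (0.0533) or near-term ductus replicate 3 (0.0587) and was 1.67 with normexp and 4.61 on the arrays with a limit under 1.5, and the others except NPY1R, PRLH and SNAI2 failed with 2 to 7 arrays left out (up to 0.168).

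In newborn lambs of 12 hours, IL6, an inflammatory cytokine gene, was at least 42.4-fold higher in the ductus than in the aorta, where it was well above background on 0 of 4 arrays (adjusted p = 2.07e-07). VEGFA, the main endothelial growth factor gene, was 26.9-fold higher (4.75 ± 0.72, adjusted p = 0.000279, 2 of 4 aorta arrays above background), at 4.16 and 5.61 without newborn aorta replicate 2 or 4. IL1A was 23.0-fold higher (4.53 ± 0.73, 0.000522, 2 of 4 aorta arrays), at 3.74 and 5.33 without these. PTGS2 was 20.5-fold higher, at 1.92 ± 0.33 (SD, n = 4) against −2.44 ± 0.54 (adjusted p = 2.44e-08), on the brighter of its 2 probes only. SLC2A3, which encodes the glucose transporter GLUT3, was 19.4-fold higher, at 5.70 ± 0.28 against 1.43 ± 0.26 (2.44e-08). CHI3L1, a secreted glycoprotein gene of activated macrophages and smooth muscle, was 7.68-fold higher (adjusted p = 0.000144). The endothelial adhesion receptor gene SELP was 6.42-fold higher (0.000144), with a log2 difference of 1.861 to 2.91 under the alternatives. The neuropeptide gene GAL was at least 2.15-fold higher (0.00765).

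Lower in the newborn ductus was ALB, which encodes serum albumin (at least 6.92-fold, adjusted p = 0.0342), with a fitted log2 difference of −3.873 to −1.445 under the alternatives. The neutrophil cathelicidin genes CATHL1B (adjusted p = 0.031) and BAC5 (0.0467) were also lower. Each of these cathelicidin genes was well above background on 1 of 4 ductus arrays, so that the size was uncertain, at −4.30 to −1.68 for CATHL1B and −3.73 to −1.54 for BAC5 under the alternatives. Without newborn ductus replicate 1, the array that measured BAC5, the differences were −4.55 and −4.15. The BMP antagonist gene CHRD (at least 2.05-fold, adjusted p = 0.0459) and the peroxidase gene LPO (at least 2.5-fold, 0.0134) were lower too. Lower as well were the receptor kinase gene ERBB2 (5.98-fold, 0.0239) and NPY1R (5.28-fold, 0.000131). In all, 1416 probes passed, 721 higher and 695 lower, with 71 named genes higher and 29 lower. A spike-in detection limit above 1.5 was found on 0 of the 4 ductus and 2 of the 4 aorta arrays. For the genes described here as higher or lower, the arrays of the vessels did not overlap, except for HYAL2 and HOXA4.

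Inflammatory genes lay higher as a group: 10 of 18 passed as higher and 1 as lower (10 and 2 when adjusted over the list alone), among them PTX3, a pattern recognition protein (1.76 ± 0.29, adjusted p = 0.000596). Of 8 immediate early genes 4 were higher, JUNB (2.45 ± 0.41, adjusted p = 0.000771), ZFP36 (1.61 ± 0.29, 0.0016), EGR1 (1.59 ± 0.34, 0.00524) and FOS (2.68 ± 0.65, 0.0128). Of 7 hypoxia response genes 3 were higher, SLC2A3, VEGFA and LDHA (1.83 ± 0.26, adjusted p = 0.000247). Of 6 glycolytic enzymes 4 were higher, LDHA, GAPDH (1.39 ± 0.26, 0.00193, 4 of 5 probes in this direction), PFKL (1.43 ± 0.33, 0.00892) and HK1 (2.17 ± 0.64, 0.0362). The lists lay above other genes in camera, inflammation at adjusted p = 1.65e-05 and the other 3 at 0.000574, and each at adjusted p = 0.135 with an estimated correlation.

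Of 9 prostanoid genes PTGS2 and PTGS1 (0.87 ± 0.20, adjusted p = 0.0103) were higher (3 genes with median centring or quantile normalisation). SLCO2A1 differed by 0.81 ± 0.33 (0.124) and PTGER4, above background on 0 of 4 ductus arrays, by at least 2.4-fold in favour of the aorta without passing (0.217). Of 11 vasoactive genes EDN1 was higher (3.33-fold, adjusted p = 0.00266) and NPY1R and AGTR1 lower (−1.22 ± 0.37, 0.0429), AGTR2 differing by 1.40 ± 0.56 (0.114). Among 9 genes of the provisional matrix the protease inhibitor gene TIMP1 was 4.63-fold higher (adjusted p = 4.49e-07) and the hyaluronidase gene HYAL2 1.48-fold higher (0.0429). Of 6 patterning genes SNAI2, HOXA4 and HOXA5 were higher, by 1.04, 1.04 and 1.05 on the log2 scale (adjusted p = 0.00265, 0.0217 and 0.0461), and the list did not pass in camera (0.0807).

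Of 3 fibroblast markers, all 3 higher when adjusted over the list alone, C3 (2.63 ± 0.39, adjusted p = 0.000239) and DCN (1.31 ± 0.25, 0.00265) were higher. NOS3 was higher among 6 endothelial markers (1.60 ± 0.35, 0.00589), CD86 among 8 macrophage markers (1.38 ± 0.34, 0.0138) and CXCR4 among 6 lymphocyte markers (1.92 ± 0.32, 0.000604), with 2 lymphocyte markers higher when adjusted over the list alone. Called endothelial markers numbered 2 with quantile normalisation, lymphocyte markers 2 with median centring and 0 with normexp, and macrophage markers 0 with normexp. Over the 17 measured leukocyte markers, which also hold those of neutrophils, 2 were higher, 7 lay above 0 and the median difference was −0.50. The median over all tested probes was −0.28. The endothelial, macrophage and lymphocyte lists did not pass in camera (adjusted p = 0.226, 0.347 and 0.586). The calls numbered 857 without newborn ductus replicate 1, where CD86 reached 0.0526, and 930 without newborn aorta replicate 3, the immediate early list also failed on the arrays with a limit under 1.5 (0.0643), and BAC5, CATHL1B, CHRD, ALB, ERBB2, HK1, HOXA4, HOXA5, AGTR1 and HYAL2 lost their calls with 4 to 7 of the 8 arrays left out (up to 0.15) and under 1 to 6 of 14 or 15 alternatives (up to 0.395), FOS reaching 0.0501 without newborn ductus replicate 3. GAL (0.33, adjusted p = 0.651 with normexp), LPO, CXCR4, CD86, FOS, PFKL, PTGS1, SNAI2, EDN1, NOS3, EGR1, DCN and GAPDH failed under 1 or 2 alternatives (the others up to 0.193), while IL6, VEGFA, IL1A, PTGS2, SLC2A3, CHI3L1, SELP, NPY1R, PTX3, JUNB, ZFP36, LDHA, TIMP1 and C3 passed under each alternative and with each array left out, although the fitted 6.57 of IL6 became 2.94 with normexp and the values of VEGFA and IL1A were 2.35 and 2.27 with normexp and 6.25 and 5.82 on the arrays with a limit under 1.5.

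At all 3 stages the ductus was higher for EDN1 and IL1A and lower for NPY1R, the named genes among 32 probes called higher and 12 called lower throughout. Independent lists of these lengths would share 0.0252 and 0.00632 probes. A slide column effect common to all slides would be shared as well. The preterm and near-term contrasts shared 40 higher and 15 lower calls (0.489 and 0.127 expected). The near-term and newborn contrasts shared 65 and 44 (4.89 and 3.28 expected), with SNAI2, TNFRSF11B and IGFBP2 among the named genes higher and AQP3 among the lower in the latter pair. The probes called at all 3 stages numbered 24, 29 and 29 without near-term ductus replicate 3, 1 or 4, 27 without near-term aorta replicate 2 or 3, 26 without preterm aorta replicate 1 or 2, and 29 without preterm aorta replicate 3. With normexp 16 were called at all 3 stages, and neither EDN1 (1.30, 0.79 and 0.96 at the 3 stages) nor NPY1R (−0.85, −0.83 and −1.58) passed near term (adjusted p = 0.433 and 0.862).

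**Figure D3:**
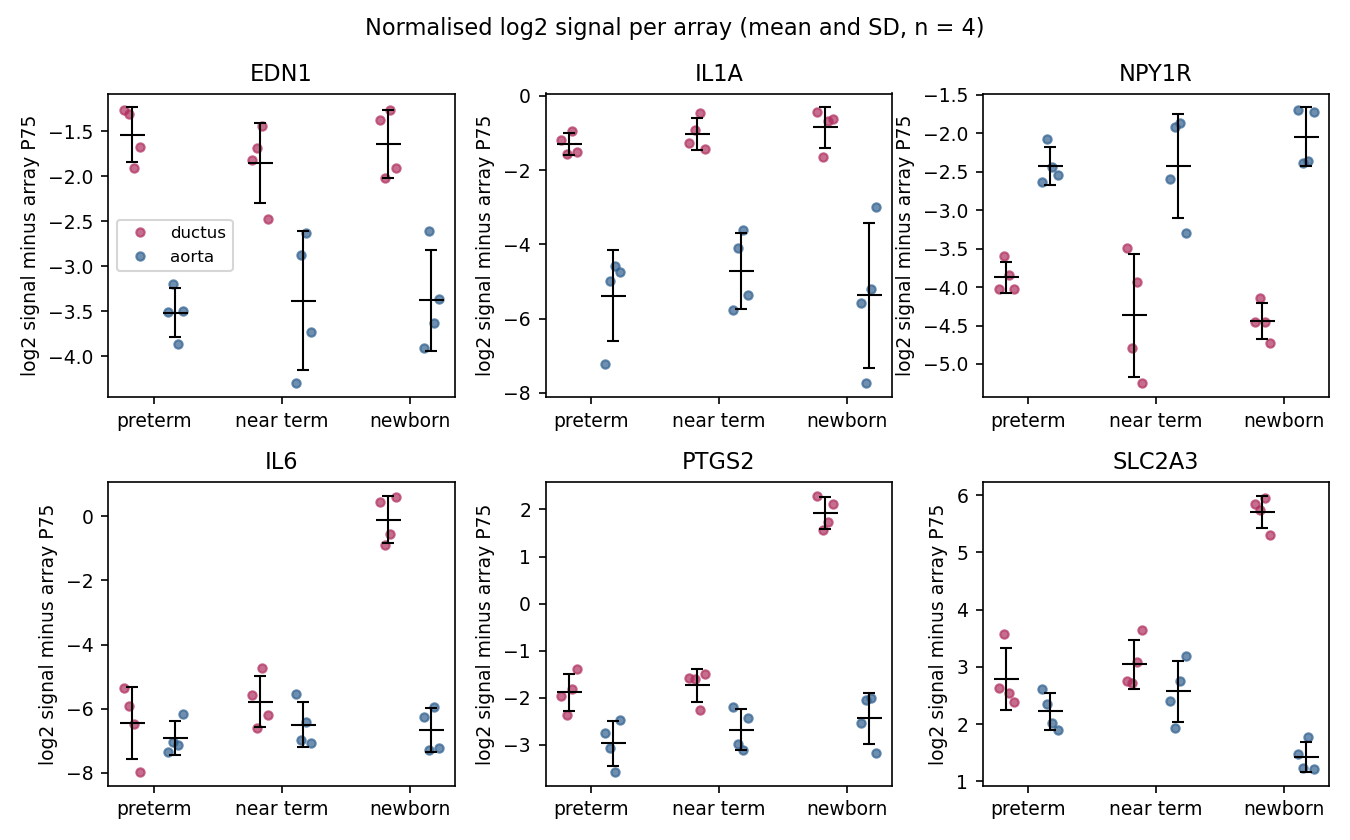
Normalised log2 signal (log2 processed signal minus the 75th percentile of the array) of EDN1, IL1A, NPY1R, IL6, PTGS2 and SLC2A3 in ductus and aorta at the 3 stages, with 1 point per array and bars for the mean and SD of 4 arrays. The ductus lies above the aorta for EDN1 and IL1A and below it for NPY1R at every stage, while IL6, PTGS2 and SLC2A3 have their highest group means in the newborn ductus; IL6 was well above background on 0 of the 12 aorta arrays.

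Between the preterm and near-term ductus 2 named genes passed, both lower near term. MMP2, which encodes the matrix protease gelatinase A, was 1.95-fold lower near term, at −0.60 ± 0.14 (SD, n = 4) against 0.36 ± 0.13 (adjusted p = 0.00348). IGFBP2 was 2.29-fold lower (−1.19 ± 0.26, 0.0495). In both genes the 4 near-term arrays lay below the 4 preterm arrays, and 0 named genes passed as higher. Calls numbered 44 probes, 22 higher and 22 lower, while 1582 of 13997 had an unadjusted p under 0.05.

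Ribosomal protein genes lay lower near term, 12 of 13 below 0 (11 with normexp) with 0 passing singly, RPL13 differing by −0.52 ± 0.22 (adjusted p = 0.386) and RPL4 by −0.33 ± 0.15 (0.425). This list passed in camera (adjusted p = 1.21e-05, and adjusted p = 0.671 with an estimated correlation). Of 4 smooth muscle contractile genes 0 passed over all probes and 2 were higher over the list alone. The myosin light chain kinase gene MYLK differed by 1.87 ± 0.57 (0.192), with preterm ductus replicate 4 far below the other 3, and the calponin gene CNN1 by 0.56 ± 0.20 (0.296). Of 9 provisional matrix genes MMP2 was lower, and of 9 prostanoid genes 0 passed, PTGS1 differing by −0.58 ± 0.20 (0.288) and SLCO2A1 by 0.72 ± 0.33 (0.43). AGTR2 differed by −1.76 ± 0.56 (0.218). The calls numbered 14 and 11 without near-term ductus replicate 1 or 3 and 26, 28 and 14 without preterm ductus replicate 2, 3 or 4, the ribosomal call ended under 3 of 17 alternatives, and 2 of the 35 splits of the 8 arrays, the real one included, called as many probes. MMP2 passed whichever array was left out but failed with normexp (0.0922), median centring (0.0823), only the groups compared (0.241) and only the arrays with a limit under 1.5 (0.243), and IGFBP2 lost its call with any array left out (up to 0.197) and under 4 of 15 alternatives (up to 0.451).

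The near-term and newborn ductus were compared to describe the first 12 hours after birth. IL6 was higher in the newborn ductus (adjusted p = 1.15e-06), by a size left uncertain because 1 of 4 near-term arrays was above background (5.67 ± 0.54 on the log2 scale, and 2.30 with normexp). The neutrophil chemokine gene CXCL8 was 21.9-fold higher, at 0.68 ± 0.32 (SD, n = 4) against −3.78 ± 0.39 (adjusted p = 5.24e-08). The transcription factor gene JUNB was 12.8-fold higher (1.07e-05) and PTGS2 12.6-fold higher (1.9e-07, 1 of its 2 probes). PTX3 was 10.6-fold higher (2.63e-07), CHI3L1 9.79-fold higher (3.95e-05), the mitochondrial superoxide dismutase gene SOD2 9.6-fold higher (2.63e-07) and SELP 8.11-fold higher (3.82e-05). PRLH was 5.56-fold lower (−2.48 ± 0.39, adjusted p = 0.000404), the mitotic spindle gene ASPM 4.95-fold lower (0.00708), TPSB2 4.41-fold lower (3.77e-05) and the hyaluronan receptor gene HMMR 4.35-fold lower (5.7e-05).

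Other falls were bounds, because the newborn ductus was not above background: the glutamate receptor gene GRIA3 by at least 2.74-fold (adjusted p = 0.0197), the kinase gene PRKAA2 by at least 1.49-fold (0.0383), ADIG by at least 1.17-fold (0.04) and the fungal glucan receptor gene CLEC7A by at least 3.74-fold (0.0493). The fitted log2 change of CLEC7A ran from −3.078 to −0.835 under the alternatives, so its bound holds for the main processing only. Calls numbered 1515 probes, 612 higher and 903 lower, with 51 named genes higher and 38 lower. For those named here the arrays of the stages did not overlap, except for HYAL2. A spike-in detection limit above 1.5 was found on 2 of the 4 near-term and 0 of the 4 newborn arrays. Of 18 inflammatory genes 8 rose and 0 fell (6 and 1 with normexp), and 10 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.54e-09, and adjusted p = 0.0967 with an estimated correlation). Of 8 immediate early genes JUNB, ZFP36 (1.93 ± 0.29, adjusted p = 0.000282) and MYC (1.67 ± 0.36, 0.00485) rose, and 5 were higher over the list alone (camera 0.000402, and adjusted p = 0.145 with an estimated correlation). Of 7 hypoxia response genes SLC2A3 (2.66 ± 0.29, adjusted p = 7.05e-06) and LDHA (0.99 ± 0.26, 0.0219) rose (4 genes with median centring or quantile normalisation, 3 with 2 falling with normexp), 3 were higher over the list alone and VEGFA differed by 2.2 ± 0.72 (0.0555). The hypoxia list passed in camera (0.0109, and adjusted p = 0.222 with an estimated correlation).

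Of 7 chaperone and unfolded protein response genes the small heat shock protein gene CRYAB rose (1.40 ± 0.27, adjusted p = 0.00225) and 4 were higher over the list alone, XBP1 differing by 0.41 ± 0.15 (0.0818) and HSPA5 by 0.42 ± 0.15 (0.0865). Of 9 apoptosis genes MCL1, which promotes survival (1.92 ± 0.23, 2.16e-05), and the death receptor gene FAS (1.55 ± 0.34, 0.00588) rose. Both lists passed in camera (0.0112 and 0.013, and adjusted p = 0.204 each with an estimated correlation). Both measured cell cycle genes fell, TYMS by 1.92 ± 0.38 (adjusted p = 0.00253) and PCNA by 1.08 ± 0.28 (0.0186). TIMP1 was 5.47-fold higher (adjusted p = 1.33e-07) and HYAL2 1.5-fold higher (0.0356), and 3 of 9 provisional matrix genes fell with normexp, against 1. Of 9 prostanoid genes only PTGS2 rose (2 genes with median centring, and with normexp 5 were also called lower), PTGER4, above background on 0 newborn arrays, being at least 2.79-fold lower without passing (0.153). EDN1 differed by 0.21 ± 0.34 (0.675).

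Of 8 macrophage markers CD14 rose (1.51 ± 0.21, adjusted p = 8.09e-05), and 2 rose and 1 fell with normexp. CYBB differed by −1.22 ± 0.42 (0.0692), 1 being higher and 1 lower over the list alone. All 5 striated muscle markers lay below 0, all 5 passing over the list alone and 1 over all probes (0 with quantile normalisation and 5 with normexp), the myoglobin gene MB (−1.68 ± 0.40, 0.0107), with MYH2 at least 2.86-fold lower without passing (0.0857). The striated muscle list did not pass in camera (0.0894). The calls numbered 921 without near-term ductus replicate 3, where PCNA reached 0.0508, 940 without near-term ductus replicate 1 and 938 without newborn ductus replicate 1, the share called higher depended on the scaling, 782 of 1371 with quantile normalisation and 667 of 4959 with normexp, and the chaperone, apoptosis, immediate early and hypoxia calls ended under 6, 3, 2 and 2 of 16 or 17 alternatives (adjusted p up to 0.311). GRIA3, LDHA, PRKAA2, ADIG, CLEC7A and HYAL2 lost their calls with 3 to 6 of the 8 arrays left out (up to 0.178) and, except GRIA3, under 4 to 7 of 14 or 15 alternatives (up to 0.309), FAS (0.26, 0.61 with normexp) and PCNA failed under 3, ASPM and MB with quantile normalisation (0.174 and 0.114) and CRYAB, MYC and TYMS on the arrays with a limit under 1.5 (up to 0.0958), while the other genes named as rising or falling passed throughout, although normexp gave 2.98 for CXCL8, 2.51 for PTX3, 3.01 for PTGS2, 1.58 for SELP and −1.66 for PRLH.

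In the aorta between preterm and near term, FABP4, a fatty acid binding protein gene of adipocytes and some endothelium, was 9.04-fold higher (3.18 ± 0.55, adjusted p = 0.011), with near-term replicate 4 at 1.63 and the other 3 at −1.75 to −1.31. HSD11B1, which regenerates active glucocorticoid, was 3.64-fold higher (1.86 ± 0.40, adjusted p = 0.0412). ALDH1A1 was 2.45-fold higher (1.29 ± 0.26, 0.0279) and HACD1, an enzyme of very long chain fatty acid synthesis, 1.87-fold higher (0.90 ± 0.19, 0.0352). IGFBP2 was 3.59-fold lower, at 1.77 ± 0.31 (SD, n = 4) against 3.62 ± 0.31 (adjusted p = 0.00119). PTGS1 was 2.02-fold lower (−1.01 ± 0.20, 0.0279) and MMP2 1.65-fold lower (−0.72 ± 0.15, 0.0279). For these 7 genes, all the named genes that passed, the arrays of the stages did not overlap.

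Calls numbered 69 probes, 32 higher and 37 lower. All 10 adipocyte markers lay above 0 (8 of 10 with quantile normalisation and 9 with median centring), with FABP4 passing, 2 higher over the list alone and LPL differing by 1.55 ± 0.45 (adjusted p = 0.162), PPARG by 1.31 ± 0.56 (0.405) and the brown fat gene UCP1 by 3.01 ± 1.44 (0.478). This adipocyte list passed in camera (0.00505, and adjusted p = 0.632 with an estimated correlation). Of 7 chaperone genes 6 lay below 0 and 0 passed over all probes, HSPA5 differing by −0.67 ± 0.15 (0.0636) and PDIA4 by −0.55 ± 0.20 (0.281), and 2 were lower over the list alone. The chaperone list passed in camera as lower (0.000389, and adjusted p = 0.124 with an estimated correlation). Ribosomal genes also passed as lower (0.0375, and adjusted p = 0.721 with an estimated correlation) with 0 of 13 passing singly, RPL6 differing by −0.32 ± 0.17 (0.572).

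Of 7 glucocorticoid response genes HSD11B1 passed (0 with normexp, quantile normalisation or median centring), 2 were higher over the list alone, all 7 lay above 0 (5 with quantile normalisation and 6 with median centring), and CEBPB differed by 1.05 ± 0.33 (adjusted p = 0.201). The list did not pass in camera (0.0943). Of 9 prostanoid genes PTGS1 alone passed (0 with median centring). The calls numbered 18, 28, 30 and 37 without preterm aorta replicate 1, 2, 3 or 4 and 30, 27 and 27 without near-term aorta replicate 1, 2 or 3, and the adipocyte, ribosomal and chaperone calls ended under 6, 8 and 2 of 16 or 17 alternatives (up to 0.73), the first also without near-term aorta replicate 4 (0.0575) and the second with 5 of the 8 arrays left out (up to 0.17). IGFBP2 failed only on the arrays with a limit under 1.5 (0.0716), FABP4 failed without preterm aorta replicate 1 (0.0529), with normexp (2.03, 0.0543) and with only the groups compared (0.206) and was 2.37 without near-term aorta replicate 4, HSD11B1 and HACD1 failed with any array left out (up to 0.168) and under 6 and 5 of 15 alternatives (up to 0.557), and PTGS1, MMP2 and ALDH1A1 failed with 5 to 7 arrays left out (up to 0.112) and under 3 or 4 alternatives (up to 0.364).

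In the aorta between near term and 12 hours after birth, CXCL8 was 7.96-fold higher in the newborn, at −0.70 ± 0.85 (SD, n = 4) against −3.69 ± 0.20 (adjusted p = 7.53e-05). JUNB was 3.3-fold higher (1.72 ± 0.41, adjusted p = 0.0165), TNFRSF11B 3.07-fold higher (1.62 ± 0.26, 0.0014). The inhibin subunit gene INHA was 2.94-fold higher (1.56 ± 0.24, 0.00104) and CRYAB 2.32-fold higher (1.21 ± 0.27, 0.0112). Under the alternatives the log2 difference ran from 1.113 to 2.878 for JUNB and 1.203 to 2.285 for TNFRSF11B. For INHA it ran from 0.747 to 2.049 and for CRYAB from 1.056 to 1.889. ASPM was 6.26-fold lower (−2.65 ± 0.52, adjusted p = 0.00493, 2 of 4 newborn arrays above background), AGTR2, an angiotensin receptor gene of fetal vessels, 5.01-fold lower (−2.33 ± 0.56, 0.0164, 3 of 4) and the neuropeptide precursor gene PMCH 3.95-fold lower (−1.98 ± 0.30, 0.00101, 3 of 4). TYMS was 3.88-fold lower (−1.96 ± 0.38, 0.00457) and BEGAIN at least 1.69-fold lower (0.0219). The elastic fibre gene FBLN1 was 2.55-fold lower (adjusted p = 0.00292). The Notch ligand gene JAG1 was 1.93-fold lower (0.029).

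Calls numbered 902 probes, 430 higher and 472 lower, with 22 named genes higher and 18 lower. The arrays of the stages did not overlap for those named here as passing. Of 7 chaperone genes CRYAB, HSPA5 (0.66 ± 0.15, adjusted p = 0.0151) and XBP1 (0.55 ± 0.15, 0.0328) rose (0 genes with median centring and 2 with quantile normalisation), and the list passed in camera (0.000141, and adjusted p = 0.0864 with an estimated correlation). Of 18 inflammatory genes only CXCL8 rose (3 genes with quantile normalisation and 2 with normexp), PTX3 differing by 0.86 ± 0.29 (0.0837), and the list passed in camera (0.00866, and adjusted p = 0.882 with an estimated correlation), its median of 0.24 turning to −0.24 with normexp. Of 8 immediate early genes only JUNB rose, with 2 higher over the list alone, MYC differing by 1.10 ± 0.36 (0.0725). Of 2 cell cycle genes TYMS fell and PCNA differed by −0.33 ± 0.28 (0.532). VEGFA differed by −1.73 ± 0.72 (0.178) and PTGS2 by 0.24 ± 0.30 (0.671).

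The calls numbered 494 and 582 without near-term aorta replicate 2 or 3 and 541, 478 and 1532 without newborn aorta replicate 1, 2 or 4, and 2 of the 35 splits of the 8 arrays, the real one included, called as many probes as the stages did, while the inflammation call ended under 4 of 17 alternatives (up to 0.882), normexp (0.309) among them. A fit of only the groups compared called 0 probes, so that no gene kept its call throughout: CXCL8, TNFRSF11B and ASPM failed there only (0.124 to 0.183), CXCL8 being 1.55 with normexp, JUNB there (0.177) and without near-term aorta replicate 1 (0.0539), CRYAB and FBLN1 also with median centring (0.0873 and 0.0622), INHA with normexp (0.143), TYMS on the arrays with a limit under 1.5 (0.115) and PMCH on these (0.121) and with quantile normalisation (0.0705), while AGTR2, BEGAIN, JAG1, HSPA5 and XBP1 failed under 3 to 6 of 14 or 15 alternatives (up to 0.392) and with 2 to 5 of the 8 arrays left out (up to 0.11), ASPM being −1.92 without newborn aorta replicate 3 and AGTR2 −1.69 without replicate 1.

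Whether the vessels changed differently between preterm and near term was tested as an interaction. No probe passed in limma (0 of 13997, with 224 at an unadjusted p under 0.05, and 0 with trend and robust settings). Probes were called with array weights after filling missing values and on the arrays with a limit under 1.5, both chosen after the results were seen. PTGS1 gave a difference of changes of 0.43 ± 0.29 and PTX3 of −0.76 ± 0.41 (both adjusted p = 1). All 7 chaperone genes lay above 0 (6 with quantile normalisation or normexp), HSP90AA1 at 0.52 ± 0.27 and HSPA5 at 0.41 ± 0.22. The list passed in camera (adjusted p = 0.0398, and adjusted p = 0.773 with an estimated correlation) but ended with 8 of the 16 arrays left out in turn (up to 0.321) and under 8 of 17 alternatives. The prostanoid and inflammation lists did not pass (0.911 and 0.936).

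At birth, by contrast, probes passed in limma for a difference in change between the vessels. SLC2A3 rose in the ductus by 3.80 ± 0.41 more than in the aorta on the log2 scale (adjusted p = 0.000165), PTGS2 by 3.42 ± 0.42 (0.000268, 1 of its 2 probes) and SOD2 by 3.15 ± 0.39 (0.000268), with CHI3L1 at 3.11 ± 0.59 (0.0146). The mean of SLC2A3 went from 3.05 ± 0.43 (SD, n = 4) to 5.70 ± 0.28 in the ductus and from 2.57 ± 0.54 to 1.43 ± 0.26 in the aorta. INHA went the other way (−1.60 ± 0.34, adjusted p = 0.0349). IL6 passed too (adjusted p = 0.000427), but it was well above background on 0 of 4 aorta arrays at either stage, so the size of its difference was not measured. Calls numbered 55 probes, 48 higher and 7 lower, with 10 named genes higher and 1 lower.

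Of 18 inflammatory genes IL6, PTX3 (2.55 ± 0.41, adjusted p = 0.00361) and SELP (2.61 ± 0.54, 0.0323) passed and 5 were higher over the list alone (camera 6.02e-08, and adjusted p = 0.0919 with an estimated correlation). Of 7 hypoxia response genes SLC2A3 passed (2 genes with median centring or quantile normalisation) and 3 were higher over the list alone, while VEGFA differed by 3.93 ± 1.02 (0.134; camera 4.44e-05, and adjusted p = 0.0919 with an estimated correlation). Of 6 glycolytic and 8 immediate early genes 0 passed over all probes (1 immediate early gene with normexp), and 2 and 4 were higher over their lists alone. LDHA differed by 1.35 ± 0.39 (0.219), ZFP36 by 1.58 ± 0.41 (0.134) and JUNB by 1.96 ± 0.58 (0.237). Both of these lists passed in camera (0.0058 and 0.00424, and adjusted p = 0.188 and 0.19 with an estimated correlation). Of 9 prostanoid genes PTGS2 alone passed (0 with quantile normalisation), and NOS3 differed by 1.44 ± 0.49 (0.362). The glycolysis and immediate early calls ended without newborn aorta replicate 4 (0.0852 and 0.111) and under 3 and 4 of 17 alternatives (up to 0.989 and 0.93), and the inflammation call also on the arrays with a limit under 1.5 (0.141). SLC2A3 alone passed under each alternative (3.17 to 4.07) and with each of the 16 arrays left out, whereas IL6 failed with normexp (0.207), PTGS2 with quantile normalisation (0.117), SOD2, PTX3 and CHI3L1 on the arrays with a limit under 1.5 (0.0657, 0.0762 and 0.164), CHI3L1 also with only the groups compared (0.0626), SELP under 4 alternatives (up to 0.513) and with 10 arrays left out (up to 0.0902), and INHA under 6 (up to 0.654) and with 12 (up to 0.0998).

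**Figure D4:**
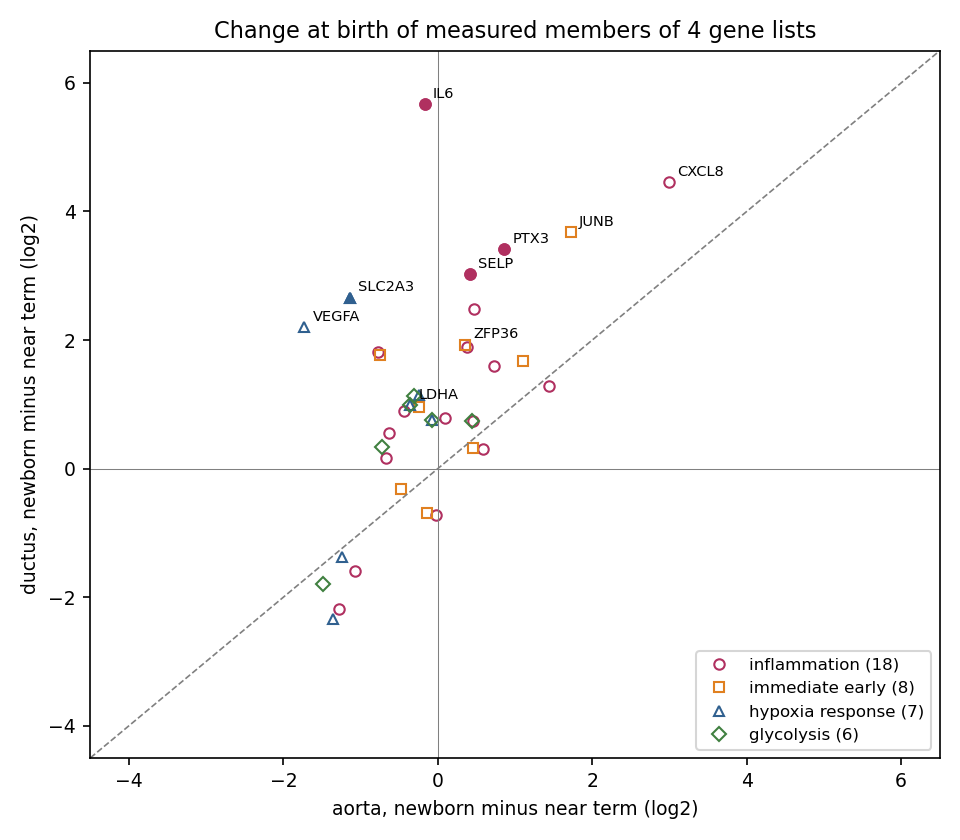
Log2 change from near term to 12 hours after birth in the aorta (x axis) and the ductus (y axis) of the measured members of the inflammation (18 genes), immediate early (8), hypoxia response (7) and glycolysis (6) lists, with filled symbols where the difference between the vessels passed at an adjusted p under 0.05 and a dashed line of equal change. SLC2A3, PTX3 and SELP carry filled symbols above the line, at differences of 3.80, 2.55 and 2.61, as does IL6, whose place is not a measured one because it was well above background on 0 of 8 aorta arrays.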

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

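Chosen after the result was seen were the tests of leukocytes, of dynamic range, of slide column, of adipose tissue and of calls shared with another comparison on other splits of the arrays, with bounds set once their values were known and the detection limit as 1 of 2 covariates tried, while the other tests on splits of the arrays were planned.

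At birth 11 named genes changed differently in the 2 vessels by the interaction in limma, with ductus minus aorta differences of log2 change of 3.80 for SLC2A3, 3.42 for PTGS2, 3.15 for SOD2, 3.11 for CHI3L1, 2.61 for SELP, 2.55 for PTX3, 2.31 for RCAN1, 1.74 for MCL1, 1.72 for TIMP1 and −1.60 for INHA. The fitted 5.85 of IL6 is not a measured size, because this gene was well above background on 0 of 8 aorta arrays; it ran from 2.85 with normexp, where the call ended, to 7.50 on the arrays with a spike-in detection limit under 1.5. RCAN1, MCL1 and TIMP1 passed at adjusted p = 0.0343, 0.0131 and 0.0029, and failed under 4, 2 and 2 of 15 alternatives (up to 0.117, 0.228 and 0.19). RCAN1 also lost its call with 11 of the 16 arrays left out (up to 0.0872), and MCL1 and TIMP1 with 0.

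Of 26 measured inflammatory and immediate early genes, 14 were higher in the newborn ductus than in the newborn aorta. Dynamic range is a candidate source, since 0 newborn ductus arrays but 2 newborn aorta arrays had a spike-in detection limit above 1.5. With that limit as a covariate 92.9% of the 14 genes kept their call, at a median of 1.78 against 1.75. As a linear term the limit therefore did not account for their difference. Among arrays under 1.5, all newborn ductus arrays included, the limit followed the first component less closely (Pearson r = 0.46) than above 1.5 (0.93). Dynamic range that the limit does not capture thus stays open. On the arrays with a limit under 1.5 only 9 of the 14 were called, at a median of 1.87, from fewer arrays. The bound for the 92.9% was set afterwards, and the 14 genes had been chosen for passing on the same arrays. That choice bears on the median as well as on the share. A slide column effect common to all slides would also show near term. There the median difference of the 14 genes was 0.16 (quartiles 0.08 and 0.40), 9.01% of that in newborns (1.75, quartiles 1.43 and 2.62). This argues against such an effect as the whole cause, although choosing genes on the newborn contrast favours a smaller difference near term. Still, 12 of the 14 lay above 0 near term, where the median of all probes was −0.12, so a small common part stays open. Leukocytes in the ductus samples stay open, because 11.8% of 17 markers (2, with an upper exact binomial 95% limit of 36.4%, above the bound of 25%) were called higher and the marker types differed, with medians of 0.21 over 8 macrophage and −1.37 over 6 lymphocyte markers. These medians depended on the scaling, at −0.175 and −0.526 with normexp and 0.184 and −0.345 with quantile normalisation. A response of the ductus to birth stays open as a hypothesis, untested, and a column effect of the newborn slide alone cannot be told apart from it.

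In the newborn ductus 903 probes were lower than near term. With the detection limit as a covariate 68% of them (614) kept their call, between the bounds of under 50% and at least 90% set afterwards for and against dynamic range as the cause. Those that lost it had a mean normalised log2 signal of −2.21 against −1.42 for those kept, and the median change of the 903 went from −1.15 to −1.01. On the arrays with a limit under 1.5, 100% of 890 lay below 0, which decides nothing because the probes had been chosen for this pattern and the newborn arrays were the same. Dynamic range and a fall after birth therefore cannot be told apart for these probes, and stage goes with slide.

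FABP4 was higher in the near-term than in the preterm aorta, and near-term aorta replicate 4 stood apart from the other 3 (1.63 against −1.75 to −1.31, Dixon ratio 0.871), as it did for PPARG (1.88 against −1.56 to −1.40, 0.952). Fat around the vessel may have entered the samples. Of the 9 other adipocyte markers 11.1% (1) were called over the list alone, while all 9 lay above 0 with a median of 0.81. The share is under the 25% and the median above the 0.5 set afterwards against this source, so it stays open. Without that array FABP4 still passed (2.37, adjusted p = 0.00425, against up to 0.206 under other alternatives), while the adipocyte list did not (0.0575).

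Single arrays stood apart in 20 of the 303 groups of gene values tested, against 15.2 by chance, and in 2 of 24 groups of array measures, by Dixon's ratio of gap to range. Preterm aorta replicate 1 had 72.1% of spots well above background against 82.7 to 84.8% (0.835), and newborn aorta replicate 4 a 75th percentile of 835 against 573.1 to 616.1 (0.836). Preterm aorta replicate 1 also stood apart for HSP90AA1 (0.879), IL1A (0.843) and RPL6 (0.902). Near-term aorta replicate 1 did for BMP6 (0.975), RPL13 (0.837) and ZFP36 (0.841), replicate 2 for PTX3 (0.863) and replicate 3 for ASPM (0.916). Newborn aorta replicate 4 did for HOXA4 (0.838). In the preterm ductus MYLK was 1.90 on replicate 4 against 5.19 to 5.29 (0.97). In the near-term ductus replicate 1 stood apart for CNN1 (0.889) and HMMR (0.834), replicate 2 for NOS3 (0.831) and replicate 3 for PTGS2 (0.878) and TNFRSF11B (0.926). In the newborn ductus replicate 1 stood apart for BAC5 (0.954), replicate 4 for CLEC7A (0.874), and replicate 2 for SELP, at −1.97 against −0.12 to −0.11 (0.997).

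Other splits of the arrays were counted for each comparison, and the share is that of splits, the real one included, with as many calls. For 35 splits 1 of 35 (0.0286) is the lowest share possible, and shares were not adjusted for the number of comparisons. The splits treat all arrays as exchangeable. That would not hold for the ductus against the aorta if arrays of equal number came from 1 animal. Swaps within such pairs were not counted. For ductus against aorta the share lay under the planned bound of 0.05 in preterm fetuses (99 probes, 1 of 35, highest other 31). It also did in newborns (1416, 1 of 35, highest other 32). For probes called at all 3 stages it was 1 of 100 draws (44, highest other 0). The share was under this bound too for the ductus after birth (1515, 1 of 35, highest other 1). So was that for the aorta between preterm and near term (69, 1 of 35, highest other 0). For the difference between the vessels at birth 2 of 100 draws, the real one included, gave as many calls (55, highest other 2532). This share is under the planned bound of 0.05. However, 100 draws are too few to place it firmly below the bound, so chance is not called excluded there. By the count of calls chance cannot be excluded for the near-term contrast (161, 2 of 35, highest other 2659), the ductus between preterm and near term (44, 2 of 35, highest other 3035) or the aorta after birth (902, 2 of 35, highest other 1838). A part of these calls was shared in direction with the comparison that had no array in common, and no other split shared as many. These were 109 near-term calls shared with the newborn contrast (1 of 35, highest other 47). In the ductus 20 were shared with the aorta between preterm and near term (1 of 35, highest other 0). In the aorta 402 were shared with the ductus after birth (1 of 35, highest other 282). A slide or slide column effect common to both comparisons would be shared too, and these splits do not address it. If both vessels came from the same animals, a chance difference between the animals of 2 stages would also be shared. Chance is therefore not called excluded for the 20 and 402 calls shared between the vessels. Chance cannot be excluded for the list tests (24 calls, 24 of 100 relabellings, highest other 40). For the difference between the vessels in maturation limma called 0 probes (224 at an unadjusted p under 0.05), so that all 100 of 100 draws gave as many, with 1 as the highest other. Splits with many times the real count point to a structure of the arrays, and the split with 3035 calls divided the arrays exactly by the detection limit.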

How the results depend on the processing

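The fits with the spike-in detection limit or the percent of spots well above background as a covariate, with only the arrays with a limit under 1.5, and with array weights after filling missing values were chosen after the results were seen. Counts below are probes called, with the 9 comparisons' main counts being 99, 161 and 1416 (ductus against aorta, preterm, near term and newborn), 44 and 1515 (ductus, near term against preterm and newborn against near term), 69 and 902 (aorta, likewise), 0 and 55 (difference between the vessels, maturation and birth), with 44 called at all 3 stages and 24 list tests. No count moved by over 1.5 times with quantile normalisation, without the filter (15008 probes), with marked spots kept, or with the number as a fixed block between stages. The cause of the other moves was not tested, except where fewer genes or arrays entered.

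For the ductus against the aorta in preterm, near-term and newborn animals the calls were 2821, 409 and 2354 with array weights, 3051, 3221 and 3260 with weights after filling, 58, 49 and 833 with median centring, 54, 51 and 852 with normexp, 9, 13 and 103 with 1 probe per named gene, 378, 946 and 848 on the arrays with a limit under 1.5, and 33, 40 and 371 with only the groups compared. With the percent above background as a covariate they were 450 in preterm and 2299 in newborn animals, and with the detection limit 153 and 2320. Called at all 3 stages were 138, 255, 20, 16, 3, 28 and 7 under the first 7 of these settings, and 73 with the percent above background.

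Between preterm and near-term ductus, newborn and near-term ductus, preterm and near-term aorta, and newborn and near-term aorta, the calls were 4027, 6882, 1041 and 2330 with array weights, 6793, 8904, 2020 and 3384 after filling, 1, 87, 7 and 33 with 1 probe per named gene, 0, 612, 286 and 1487 on the arrays with a limit under 1.5, and 2, 871, 12 and 0 with only the groups compared. Median centring gave 12 in the maturing ductus, 14 in the maturing aorta and 181 in the aorta after birth, and normexp 28 in the maturing ductus and 4959 in the ductus after birth. In the maturing ductus and aorta trend and robust settings gave 83 and 106 and the filter on all 24 arrays (8998 probes) 106 and 117, and the percent above background gave 130 in the maturing ductus. For the difference in maturation 2382 were called with weights after filling and 13 on the arrays with a limit under 1.5. For the difference at birth 130 were called with array weights, 1438 after filling, 33 with median centring, 12 with 1 probe per named gene, 153 on the arrays with a limit under 1.5, 101 with the percent above background and 96 with the detection limit. The 2 sets of weights disagreed, running from 0.293 (newborn aorta replicate 4) to 4.90 (near-term aorta replicate 2) and from 0.258 (near-term ductus replicate 2) to 10.1 (near-term ductus replicate 3). On the arrays with a limit under 1.5 preterm, near-term and newborn aorta kept 1, 1 and 2 arrays and preterm, near-term and newborn ductus 2, 2 and 4, and a lone array is assumed to vary like the other groups. The counts of this fit stand largely for other probes. In every comparison with calls, most calls of the main fit, higher or lower, were not called there.

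List calls numbered 0 with an estimated correlation, 14 with the filter on all 24 arrays and 15 on the arrays with a limit under 1.5, where the immediate early list at birth also turned its direction (adjusted p = 0.93). The filter on all 24 arrays left the patterning, adipocyte and hypoxia response lists, among others, with under 5 members. These were not tested there, so their calls are missing rather than lost, while 7 list calls were lost and 3 gained. The labels do not pair the vessels by number. Of 12 pairs of equal number 6 had deviations correlated above 0.1 and 5 below −0.1 (−0.59 to 0.82), and 5 correlated best with their own number; after removing the detection limit 10 lay above 0.1 (0.05 to 0.43) and 11 were best with their own, a hint from the data only, since arrays of a stage with equal number also lie in 1 row of the slide. With stage and number as a fixed replicate block the calls were 185 in preterm and 264 in near-term animals, 89 for the difference at birth and 75 at all 3 stages. As a random replicate block (correlation 0.178) they were 213, 272 and 2199 in preterm, near-term and newborn animals, 132 at birth and 83 at all 3 stages. Slide as a block was not run, because each stage lies on 1 slide: a fixed slide term lies within the group means and a random one cannot be estimated.

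With 1 array left out the calls ran from 52 to 85, 70 to 156 and 857 to 1592 for the ductus against the aorta, 11 to 54 and 921 to 2171 between stages of the ductus, 18 to 53 and 478 to 1532 between stages of the aorta, 39 to 63 for the difference at birth, 24 to 45 at all 3 stages and 22 to 28 for lists, and stayed at 0 for maturation. Median centring moved the percent of calls that were higher from 72.7 to 87.9, 59 to 75.5 and 50.9 to 68.5 for the ductus against the aorta, 50 to 25 and 40.4 to 60.7 between stages of the ductus, and 72.7 to 90 at all 3 stages. Quantile normalisation gave 57 and normexp 13.5 for the ductus after birth, and normexp 87.5 at all 3 stages. The median change of all probes in the ductus after birth was −0.31, and 0, −0.02 and −0.53 with median centring, quantile normalisation and normexp, against which such changes are to be read; in the other comparisons it ran from −0.28 to 0.22 as normalised. Called named genes kept direction and call 2299 times over all settings and lost the call 497 times, while uncalled ones stayed uncalled 4455 times in the same direction and 144 times in the other and gained a call 266 times. Of 119 calls of named genes 32 held under every alternative and every array left out, 85 ended under at least 1 alternative, and 58 had a fold that moved by over 1.5 times under at least 1, 50 of these with normexp. Called lists kept their call 528 times and lost it 105 times, with 1 more turning sign as it lost its call, and uncalled ones stayed so 4152 times in the same direction and 341 in the other and gained a call 85 times. Signal over background limits what can be read from dim probes.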

Other observations

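No test was chosen for this part after the result was seen, but the genes below were picked from the lists of shared calls after these were known.

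Both vessels shared many calls between near term and 12 hours after birth. The ductus and aorta shared 181 probes called higher, against 18.8 for independent lists, and 221 called lower, against 30.5. These 2 comparisons have no array in common, but both set the newborn slide against the near-term slide. A slide effect common to both vessels would therefore be shared as well. The labels also leave open whether both vessels came from the same animals. Among the named genes shared as higher were the monocyte receptor gene CD14, CXCL8, JUNB, CRYAB, FABP4, TIMP1 and TNFRSF11B. CXCL8 rose 21.9-fold in the ductus and 7.96-fold in the aorta, with a difference between the vessels that did not pass (1.46 ± 0.45, adjusted p = 0.273). CRYAB rose 2.64-fold and 2.32-fold (difference 0.19 ± 0.39, adjusted p = 0.91).

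Among the named genes shared as lower were ASPM, which organises the mitotic spindle, TYMS, which makes thymidylate for DNA synthesis, and HMMR, a hyaluronan receptor gene. ASPM fell 4.95-fold in the ductus and 6.26-fold in the aorta, and TYMS 3.79-fold and 3.88-fold, and the differences between the vessels did not pass (0.34 ± 0.74, adjusted p = 0.913, and 0.04 ± 0.54, 0.989). PCNA, the other measured member of the cell cycle list, passed in the ductus but not in the aorta (−0.33 ± 0.28, adjusted p = 0.532), with a difference that did not pass (−0.74 ± 0.40, 0.719). TPSB2, IGFBP2, PMCH, APOA1, CCR3 and PFKM were lower in both as well. Between preterm and near term the vessels shared 8 probes called higher (0.0503 for independent lists) and 12 called lower (0.0582), IGFBP2 and MMP2 among the latter. Here too both comparisons set the same slides against each other.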
